A study of Brassica napus with 2 samples.

How the data were processed

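Small RNAs were sequenced from roots of oilseed rape (Brassica napus, an allotetraploid carrying the A genome of B. rapa and the C genome of B. oleracea). Per the labels' protocols, 10-day-old plants of the cultivar Express 617 had their roots dipped in a suspension of conidia of Verticillium longisporum, a soil-borne fungus that enters through the root, or in water as the mock treatment. Roots were taken after 6 days, RNA of the plants was mixed within each treatment, and 1 small RNA library per treatment was made with a standard Illumina protocol. Groups were taken from the infection label, which gave 1 mock and 1 infected library.

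The authors deposited whole-number read counts per distinct small RNA sequence, in 1 listing per library for each of the A and C genomes, per the labels and the series title. The listings had no header line and carried a running number, a count and a sequence. The running number followed falling abundance in both libraries, so it was read as the rank of a sequence in its library. Adapter trimming, the aligner, the genome versions, the mismatches allowed and the choice of listed sequences are not given in the sources used here. Up to the last listed rank, the listings covered 0.890% of the ranks of the mock library and 1.06% of those of the infected library. Counts and ranks together bounded the reads up to that rank. The bounds were 16780043 and 17089704 reads for mock, and 16961792 and 17482972 reads for infected. The listed reads were 13.3% to 13.6% of these reads for mock and 13.2% to 13.6% for infected. These reads are called library totals below, and any sequences ranked after the last listed one are not in them. Many sequence groups were listed for 1 library with no counterpart for the other, so an unlisted sequence was given no value and never a count of 0. Genome coordinates and precursor annotation were not used here, and no sequence was placed on a genome.

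From the deposited counts, the A and C listings of each library were joined, with a sequence counted once, and lines repeated within a listing (10 for mock, 1 for infected) were dropped. Counts were scaled to reads per 1000000 listed reads. A ratio is infected over mock, with an exact conditional Clopper-Pearson 95% interval, and a share has a Clopper-Pearson one. Ratios of forms relative to their parents have a normal interval on the log scale. These intervals cover counting error only, since PCR reads without molecular identifiers are not independent molecules. With 1 library per group no p-value was computed, and every difference compares 2 libraries and has no replicate check. A size rule fixed before the data were examined called a family or sequence higher or lower when its ratio was at least 2 or at most 0.5, its interval lay wholly on that side of 1, and it had at least 20 reads over both libraries.

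A list of 42 conserved or Brassica miRNA families with 65 mature sequences was written from general knowledge before the data were examined, with 7 functional lists (silencing, auxin, nutrient, copper, resistance, PPR and development). It was not checked against a database. A read joined a family at an exact match, and a family sum used members listed for both libraries. A list with at least 3 measured members was set against 10000 random lists of the same size, each member drawn from the 50 sequences nearest in abundance. These sequences were listed for both libraries, had at least 20 reads over both, and included no miRNA form. Fragments of ribosomal RNA were not removed from them. A percentile therefore does not set a list against other miRNAs. The families named in the text were the 10 with most reads, up to 8 at each end of the ratios among those whose interval excluded 1, and every member of the silencing and resistance lists. Single sequences were named as the 5 highest and 5 lowest ratios among those with at least 100 reads, and the 3 most abundant of 24 nt. Other items named were chosen after their values were seen. Structural RNA was searched with a list of 5S and 5.8S rRNA and 3 tRNAs.

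Several tables were written after the listings had been read: part of plant 18S rRNA, 20 miRNA passenger strands, and 9 markers of bacterial ribosomal RNA, of which 4 were taken as not shared with plant organelles. These tables were written from general knowledge and not checked against a database. A sequence carried a marker when it held 15 consecutive bases of it. The 5S and 23S rRNA markers were written after abundant sequences carrying them had been seen, so they describe those sequences and are no independent search. Sequences that carried them, and sequences without a match to the miRNA or plant rRNA tables, are not printed.

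The alternatives listed in advance were scaling to the summed miRNA families, scaling by the median ratio, use of the A or the C listings alone, inclusion of isomiRs (the same 5′ start, at most 1 mismatch over the first 18 bases, any 3′ end, 18 to 25 nt), other read minimums, a ratio of at least 1.5, and distinct sequences in place of reads. Scaling to the library totals, scaling without the marker sequences, counting unlisted members as 0, and length or C genome shares without the marker sequences or without the forms of miR156 and miR157 were added after seeing the data. The ratio and size rule were tested on simulated data made from the 2804 sequences of the infected against mock comparison. The simulated counts were Poisson draws, which hold counting error only and no variation between libraries or plants. They therefore do not give the rate of false calls for 2 unreplicated libraries. The rule called 88 of 100 sequences changed 3-fold, 98 of 100 changed 5-fold and 31 of 2604 unchanged ones, or 1.19%, and 96.5% of the intervals held the simulated ratio. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.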

Results

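Small RNAs of mock-treated and V. longisporum-infected B. napus roots were compared 6 days after treatment, with 1 library of mixed RNA per group. The listings held 45270 distinct sequences and 2280095 reads for mock, and 44844 distinct sequences and 2313681 reads for infected. Sequences of 18 to 44 nt were present, and 63.0% of the mock and 60.6% of the infected sequences had a single read. The libraries shared 11534 sequences, which held 95.6% of the listed mock reads and 85.6% of the listed infected reads. No difference below has a replicate check, and all intervals are 95% counting intervals.

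The first comparison asked which known miRNAs differed between infected and mock roots. The miRNAs miR160, miR164 and miR390, which act on auxin response factor and NAC genes or on the TAS3 pathway, were lower in the infected library, at ratios between 0.301 and 0.452. The miRNAs miR399 and miR395, known from phosphate and sulfate starvation, were also lower, at 0.255 and 0.412. The miR1885 family, which targets a resistance gene of the TIR-NBS-LRR class in Brassica, was higher at 2.17, and miR394, which targets an F-box gene of meristem and leaf development, was higher at 2.04. The most abundant family, miR156 with miR157, which targets SPL transcription factor genes, had a ratio of 0.924, and this direction turned under 3 other scalings and with the A genome listings alone.

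Of the 42 families, 26 had members listed for both libraries and 24 reached 20 reads. By the size rule 2 were higher, 6 were lower and 16 were neither. The intervals of 17 families lay wholly below 1, those of 3 lay above 1, and those of 4 included 1. These counts hold for scaling to listed reads. Among the 17, miR156 with miR157 and miR158 had ratios above 1 under 3 other scalings and with the A genome listings alone. The median log2 ratio of the 24 families was -0.63. Over 1467 sequences with at least 20 reads in each library the median ratio was 0.828 (log2 -0.27). Scaling to the miRNA families, by the median ratio or without the marker sequences raised every log2 ratio by 0.18, 0.27 or 0.14. The families held 68.2% of the listed mock reads and 60.1% of the listed infected reads.

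**Figure D1:**
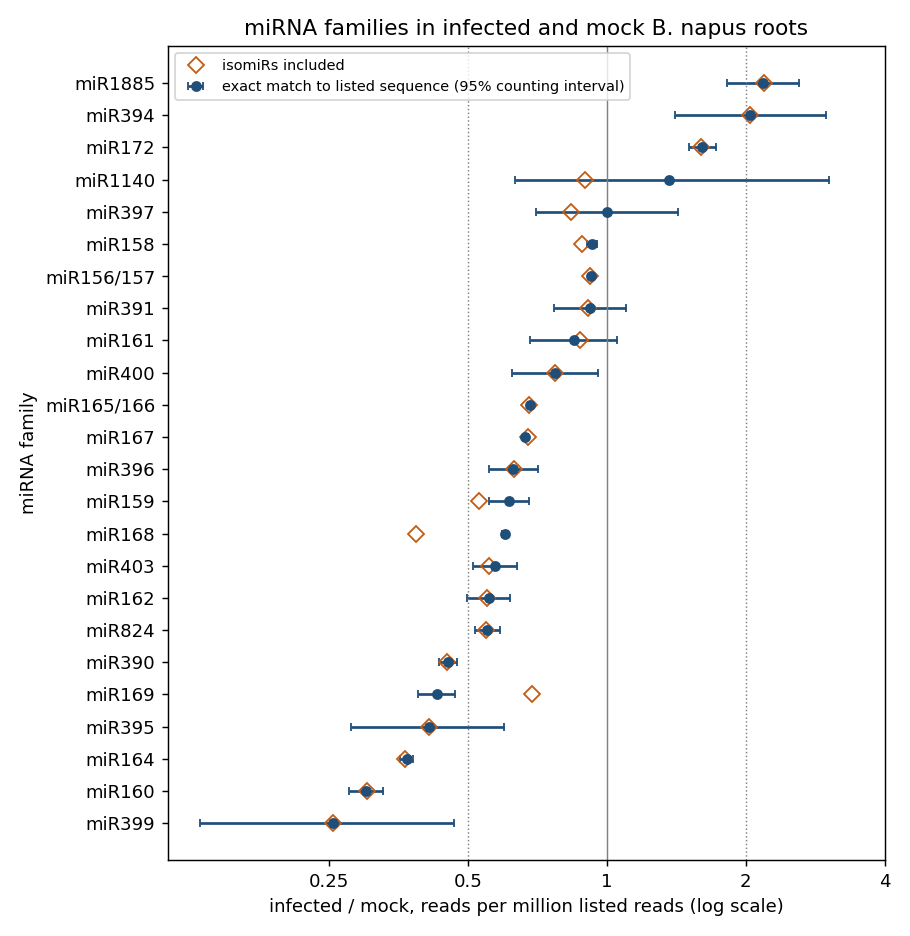
Ratio of infected over mock reads per 1000000 listed reads (log axis) for the 24 families with at least 20 reads, 1 library per group; points are exact matches with 95% counting intervals, diamonds include isomiRs, and dotted lines mark 0.5 and 2. miR1885 and miR394 lie above 2, 6 families lie below 0.5, and miR168 and miR169 differ most between the 2 ways of counting.

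Among the auxin-related miRNAs, 4 of 6 families were measured and 3 of them were lower. The count of miR160 was 2399 reads in mock and 732 in infected roots (ratio 0.301, interval 0.276 to 0.327). The miR164 family had 12678 and 4737 reads (0.368, 0.356 to 0.381), and both of its members were low, miR164a at 0.377 and miR164c at 0.328. For miR390 the counts were 6239 and 2863 (0.452, 0.433 to 0.473). The remaining measured family, miR167, which targets activating auxin response factors, had 51107 and 34536 reads and a ratio of 0.666. The median log2 ratio of the list was -1.29, at percentile 1.12 of the random lists, whose central 95% ran from -1.15 to 1.56. The random lists held no miRNA forms, and the median of all 24 miRNA families was itself -0.63. The percentile therefore does not show that the auxin list stood apart from other miRNAs. The call of miR390 was lost when scaled to the miRNA families (0.514) or by the median ratio (0.546). The miR393 family and the TAS3 tasiR-ARF had no exact match in the listings used here and so no ratio.

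In the silencing list, miR162, miR168 and miR403 target the mRNAs of DCL1, AGO1 and AGO2, which make or load small RNAs. All 3 were measured, none was called at an exact match, and all 3 intervals lay below 1. With isomiRs miR168 was called lower, at 0.385 (0.382 to 0.388). The miR162 family had 954 and 537 reads (0.555, 0.498 to 0.617), and miR403 had 899 and 523 (0.573, 0.514 to 0.639). The A-ended miR168 sequence on the list had 64053 and 39103 reads (0.602, 0.594 to 0.609). The list had a median log2 ratio of -0.80, at percentile 12.1 of the random lists, which held no miRNA forms.

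In the resistance list, miR1885 was the measured member, with 184 mock and 406 infected reads (2.17, 1.82 to 2.60), while miR472 and miR825 had no exact match in the listings used here. In the nutrient list, both families measured at an exact match were lower, each with few reads. Another member, miR827, had no exact match listed for mock, but its Brassica form had 1531 and 1428 reads (0.919, 0.855 to 0.989). The miR399 family, which targets the phosphate regulator PHO2, had 54 and 14 reads (0.255, 0.131 to 0.466). The miR395 family, which targets sulfate assimilation genes, had 98 and 41 reads (0.412, 0.279 to 0.599). With a minimum of 100 reads miR399 had too few reads for a call. In the copper list miR397, which targets laccase genes, had 66 and 67 reads, and in the PPR list miR400 and miR161 had ratios of 0.774 and 0.848, none of them called. The direction of miR161 turned with median-ratio scaling, and that of miR397 with scaling to library totals and with isomiRs.

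The development list had 7 of 9 families measured, with 1 higher and none lower. Its called member miR394 had 44 and 91 reads (2.04, 1.41 to 2.99). The miR172 family, which targets AP2-like genes, had 1355 and 2212 reads, and its ratio of 1.61 (log2 0.69, interval wholly above 1) did not meet the size rule. Its members stood apart, with miR172a at 1.73, miR172c at 1.01 and miR172e at 1.02. The family of miR165 and miR166, which targets HD-ZIP class genes of organ polarity, had 83513 and 57713 reads (0.681). The miR824 family, which targets an AGAMOUS-like gene, had 2828 and 1580 reads (0.551), and miR159 and miR396 had ratios of 0.613 and 0.627. Between miR156 and miR157, the 20-nt miR156 sequence had 453894 and 504555 reads (1.10), and the 21-nt miR157 sequence had 859570 and 726476 (0.833). The list's median log2 ratio was -0.55, at percentile 16.7 of the random lists, which held no miRNA forms.

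Among families in no list, miR169, which targets NF-YA genes, had 1567 and 680 reads (0.428, 0.390 to 0.468). This value rested on miR169b at 0.323, while miR169d was at 1.44. The Brassica form TGAGCCAAAGATGACTTGCCG, counted with the isomiRs, had 11769 and 8655 reads (0.725), and with isomiRs the family ratio was 0.689 and no longer met the size rule. The call of miR169 was also lost with median-ratio scaling (0.517, 0.471 to 0.566). The miR158 family had 11995 and 11284 reads (0.927), and its direction turned under 3 other scalings and with the A genome listings alone.

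Counting isomiRs changed the value of miR168, which then had 196145 mock and 76654 infected reads. Its most abundant form in mock roots was the C-ended TCGCTTGGTGCAGGTCGGGAC, with 104182 and 18466 reads (0.175, 0.172 to 0.177). The A-ended TCGCTTGGTGCAGGTCGGGAA was at 0.602, and the 22-nt form TCGCTTGGTGCAGGTCGGGAAC had 17363 and 14509 reads (0.823). The C-ended form made up 61.9% (61.7 to 62.2) of the C-ended and A-ended reads in mock roots and 32.1% (31.7 to 32.5) in infected roots. These forms were chosen after their values were seen. With isomiRs 2 families were higher and 6 lower of 25, and the lower set differed by miR168 in place of miR169.

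**Figure D2:**
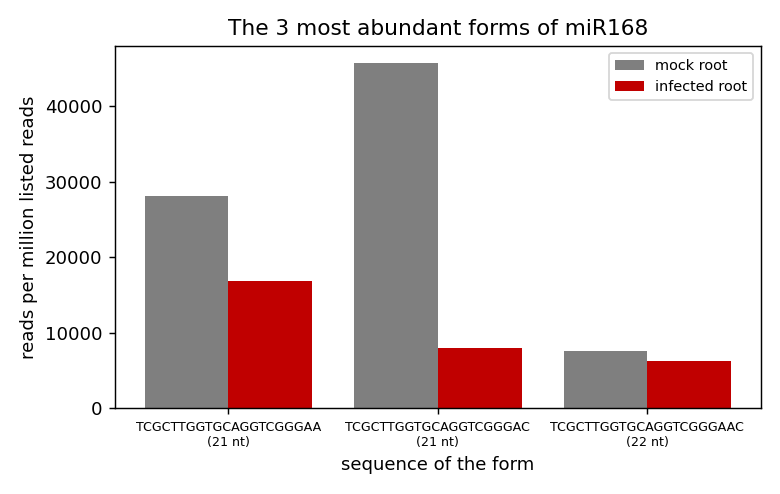
Reads per 1000000 listed reads of the 3 most abundant miR168 forms in the mock (grey) and infected (red) library, 1 library per group and no error bars. The C-ended 21-nt form is the highest bar in mock roots at 45692 and stands at 7981 in infected roots, below the A-ended form at 16901.

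The length profile asked whether small RNA classes differed between the roots. The 21-nt class, which holds most miRNAs, made up 59.5% of listed reads in mock roots (59.5 to 59.6) and 45.6% in infected roots (45.5 to 45.7). The 20-nt class was 23.02% and 26.05%, and the 24-nt class, the size of heterochromatic siRNAs in plants, was 5.22% (5.19 to 5.25) and 9.72% (9.68 to 9.76). With the A genome listings alone the 24-nt class was 2.51% and 2.72%, and the 21-nt class was 64.2% and 53.1%. Among distinct sequences the 24-nt class went the other way, at 28.8% in mock and 23.9% in infected roots. Sequences carrying markers of bacterial ribosomal RNA moved with the group, at 5.03% (4.999 to 5.056) of mock and 14.0% (14.0 to 14.1) of infected listed reads. These shares include marker sequences listed for 1 library alone, and over shared sequences the 5S and 23S rRNA markers had ratios of 2.13 and 1.98. Without the marker sequences the 24-nt share was 3.48% and 4.09%, and the 21-nt share was 62.5% and 52.1%. Without the forms of miR156 and miR157 the 21-nt share was 51.4% and 29.6%, and the 24-nt share was 12.9% and 21.5%. The marker sequences were kept in this setting, and the 2 sets were not removed together. Its 21-nt reads numbered 474410 and 309633, of which the C-ended miR168 form held 104182 and 18466. The 24-nt sequences began with A in 46.5% of mock and 48.5% of infected distinct sequences, and the 21-nt sequences began with T in 43.6% and 42.2%.

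**Figure D3:**
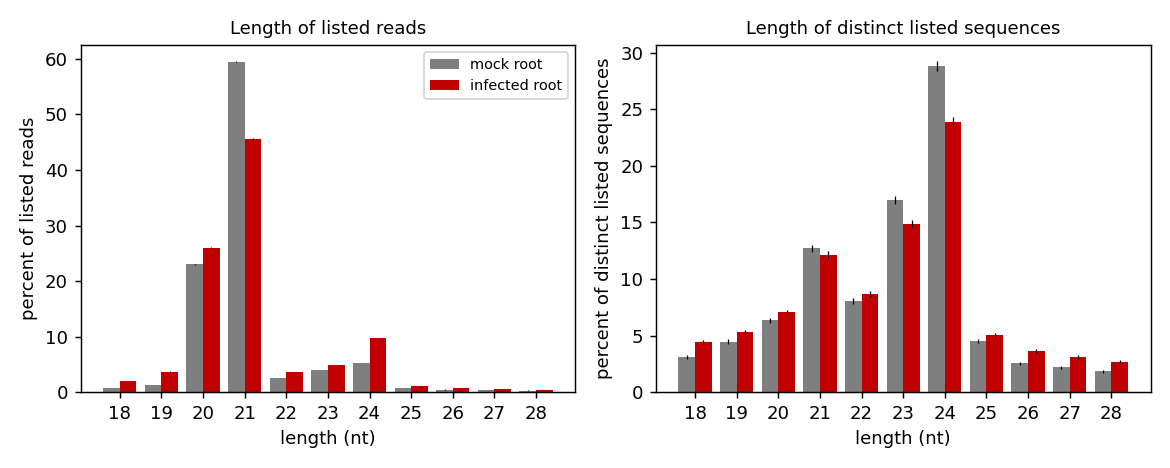
Share of listed reads (left) and of distinct listed sequences (right) at each length from 18 to 28 nt in the mock (grey) and infected (red) library, 1 library per group, with 95% counting intervals. The 21-nt share of reads is 59.5% in mock and 45.6% in infected roots, while 24 nt leads the distinct sequences at 28.8% and 23.9%.

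The A and C genome listings were compared because B. napus carries both genomes. Sequences listed for both genomes held 91.8% of the listed mock reads and 84.3% of the listed infected reads, and all 26 measured families had their counted members listed for both. Sequences listed for the C genome alone numbered 14053 in mock and 16774 in infected roots and held 8.24% (8.20 to 8.27) and 15.7% (15.6 to 15.7) of reads. Those listed for the A genome alone numbered 64 and 67. Marker-carrying sequences made up 47.6% of the reads listed for C alone in mock and 57.2% in infected roots. Those listed for C alone that carried no marker held 4.32% (4.29 to 4.34) of all listed mock reads and 6.71% (6.67 to 6.74) of all listed infected reads. Over sequences listed for both libraries, those listed for C alone had a ratio of 1.58 (1.57 to 1.59), which was 0.796 (0.786 to 0.805) without the marker sequences. For those listed for both genomes the ratios were 0.845 and 0.830.

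Single small RNAs were compared for sequences beyond the miRNA list. Of 2804 sequences listed for both libraries with at least 20 reads over both, 341 were higher and 560 were lower by the size rule. Median-ratio scaling gave 439 and 381. Sequences listed for the mock or the infected library alone had no ratio and are not in these counts. Among those with at least 1000 reads, 36 were listed for the infected library alone and 2 for the mock library alone. Of 498 miRNA forms among the 2804, 4 were higher and 165 lower, 69 of the latter being miR168 forms. These forms are variants of the listed miRNAs, 109 of them of miR168, so their calls are not independent. Of 182 marker-carrying sequences, 85 were higher and 11 lower. The lowest ratios belonged to forms of miR159 (TTTGGATTGAAGGGAGCTTA, 200 and 2 reads, 0.00985), miR168 (TCGCTTGGTGCAGGTCTGGAC, 238 and 5, 0.0207), miR167 (TGAAGCTGCCAGCATGATTA, 101 and 4, 0.0390) and miR164 (TGGAGAAGCAGGGCACGTGCT, 167 and 7, 0.0413). The next was a 30-nt fragment of plant 18S rRNA with 117 and 6 reads (0.0505). The highest ratio, 24.6 (15.4 to 41.9), belonged to a 21-nt sequence with a bacterial 23S rRNA marker, with 18 and 449 reads. The third carried a bacterial 5S rRNA marker (7 and 112 reads, 15.8), and the 3 others of the top 5 matched no table, at 20.7, 14.2 and 13.5. The most abundant 24-nt sequence carried a 5S rRNA marker and had 38899 and 125114 reads (3.17), the second matched no table (4929 and 8825, 1.76), and the third carried a 5S rRNA marker (728 and 5982, 8.10).

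Structural RNA fragments were examined as a planned sign of RNA quality. The rule that chose the listed sequences is not known, so the listed shares of these fragments cannot speak of RNA quality. The list of 5S rRNA, 5.8S rRNA and 3 tRNAs gave 1 listed read, of 5.8S rRNA in mock roots. Fragments from the 3′ region of plant 18S rRNA, added after seeing the data, made up 2.63% (2.61 to 2.65) of listed mock reads and 1.65% (1.63 to 1.66) of listed infected reads. Over the 133 of these listed for both libraries the ratio was 0.627 (0.619 to 0.635).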

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

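Of the settings here, scaling to library totals, scaling without marker sequences, unlisted members as 0, median-ratio scaling for the lists, shares without marker sequences or without miR156 and miR157, and the added 18S rRNA were chosen after seeing the data. Counts of higher families (2; 3 at a ratio of 1.5) and lower families (6; 4 to 6 elsewhere) stayed within 1.5 times, except 13 lower at a ratio of 1.5. No called family changed sign, and 176 of 192 family values under alternatives kept theirs. The 16 others belonged to miR156 with miR157, miR158, miR161, miR391, miR397 and miR1140. The family median of -0.63 became -0.45 with scaling to miRNA families, -0.36 with median-ratio scaling, -0.49 without marker sequences, -0.51 with A listings and -0.56 with isomiRs. The silencing, auxin and development medians became -0.62, -1.11 and -0.37 with miRNA scaling, and -0.53, -1.02 and -0.28 with median-ratio scaling; the 1 factor applied to every sequence makes these shifts. The 21-nt and 24-nt shares over distinct sequences were 12.7% and 28.8% in mock and 12.1% and 23.9% in infected roots. With A listings they were 64.2% and 2.51%, and 53.1% and 2.72%. Without marker sequences they were 62.5% and 3.48%, and 52.1% and 4.09%. Without miR156 and miR157, but with marker sequences kept, they were 51.4% and 12.9%, and 29.6% and 21.5%. Sequences listed for C alone without a marker were 4.32% of all listed mock reads and 6.71% of all listed infected reads, marker reads kept in these totals. A minimum of 100 reads left 127 higher and 185 lower single sequences, since fewer were tested. With 18S rRNA the structural share was 2.63% and 1.65%. For other moved values the cause was not tested. Counting reads at every genome location was not run, because locations were not used here. No paired analysis was possible because each group has 1 library. Depth limits miR399, miR394, miR395, miR397 and miR1140 most, by their few reads.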

Other observations

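The tests of explanations in this part were all chosen after the results were seen.

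Some miRNAs off the exact list were abundant. The miR827 family, a phosphate-related miRNA counted through its Brassica form TTAGATGACCATCAACAAATA, had 1531 mock and 1428 infected reads (0.919, 0.855 to 0.989), beside miR399 and miR395 of the same list at 0.255 and 0.412. The miR397 form TCATTGAGTGCAGCGTTGATGT had 1265 and 1062 reads (0.827). Of 20 passenger strands, 2 were listed: miR408-5p, from the copper-related miR408 precursor, with 7672 and 7716 reads (0.991, 0.960 to 1.02), and miR171-5p with 85 and 74 (0.858, 0.620 to 1.19). The exact miR319 sequences were listed for the infected library alone, with 45 and 9 reads.

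Groups of sequences sharing 15 bases were listed unevenly. Of 541 such groups, 337 had at least 1 sequence listed for both libraries, and 1 had sequences in each library but none shared. A further 113 were listed for infected roots alone with 8.35% of the listed infected reads, and 90 for mock roots alone with 1.46% of the listed mock reads.

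The C-ended miR168 form was lower relative to the A-ended form in the infected library, by a ratio of 0.290 (log2 -1.78). Counting error alone is argued against, since the upper bound of that ratio was 0.296. Of 16 forms of other families with a replaced last base, 12.5% reached as low a relative value, and the median of the 16 was -0.64. Those that reached it were the T-ended forms of miR164 and miR160, with 7 and 1 infected reads. Each of the 16 had fewer reads than its parent, whereas in mock roots the C-ended miR168 form (104182 reads) outnumbered the A-ended form (64053). Because the forms compared are so unlike, this test cannot decide whether a general loss of such forms took part. The C-ended form (infected over mock 0.175) also equals the 22-nt miR168 form (0.823) lacking 1 A before the last base. It can thus be read as a form with a deletion, the kind described next. It was tested only as a form with a replaced last base. Forms whose last base was replaced by T were below their parent in 8 of 9 cases (median -1.25). The other C-ended form, of miR167, was at -0.28, and 4 of the 16 were above 0. Infection and library preparation differ together here, so their parts cannot be told apart.

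Of 14 abundant miRNA sequences taken as parents, miR157, miR159, miR166 and miR167 had enough reads of forms lacking 1 or 2 internal bases. Over these 4 parents such forms were scarcer relative to their parents in the infected library. They had 1388 mock and 264 infected reads (pooled relative ratio 0.230, 0.201 to 0.262). The pattern was noticed in 3 of these forms, of miR157, miR159 and miR167, which supply nearly all such reads of miR159 and miR167. Without them 2 parents had enough reads, miR157 at 0.406 (0.337 to 0.489) and miR166 at 0.423 (0.260 to 0.688), and the pooled upper bound of 0.479 argues against counting error. Forms of the same 4 parents with substituted bases, a replaced last base not counted, had a pooled relative ratio of 1.01 (0.988 to 1.03). They stood at 2.24% of parent reads in mock and 2.26% in infected roots, so these substituted forms showed no loss when pooled. By parent they ran from log2 -0.36 for miR167 to 0.17 for miR159. Forms with the last base replaced by T were at log2 -1.39 for miR157, -0.97 for miR166 and 0.15 for miR167. A loss of other variant forms is therefore not excluded. Reads with a deletion did not follow parent abundance. In mock roots they numbered 1006 beside 859570 parent reads for miR157, 207 beside 1019 for miR159, and 3 beside 453894 for miR156. What stays open is sequencing errors that drop bases, a difference in library preparation, or a biological change in miRNA forms. No test was run to separate these.

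Sequences with bacterial 5S and 23S rRNA markers were more abundant in the infected library. A candidate explanation is rRNA of bacteria in the infected root sample. Of 4 bacterial-only markers, 2 were listed for both libraries, too few to decide, at 2.13 (5S rRNA) and 1.98 (23S rRNA) over shared sequences; over all their sequences they held 3.92% and 1.11% of listed mock reads and 8.36% and 5.03% of listed infected reads, and a second 5S marker was listed for infected roots alone with 14302 reads. The bacterial-only 16S rRNA marker matched 0 listed sequences, and a 16S rRNA marker shared with mitochondria was at 0.652 (0.637 to 0.668). The 5S and 23S markers were written after such sequences had been seen and were not checked against a database. Every sequence here came from a listing for the A or C genome, and a source other than bacteria was not tested. If the source was bacterial, root-associated bacteria cannot be told apart from bacteria brought in with the inoculum or during RNA preparation.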
